A study of Ptychodera flava with 8 samples.

How the data were processed

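ATAC-seq libraries were made from whole animals of Ptychodera flava at early blastula, early gastrula, mid gastrula and late gastrula, with 2 libraries per stage. Per the labels' protocols, embryos were pooled to 75000 cells per sample, freed of their jelly coat, lysed and treated with Tn5 transposase before PCR. Nothing in the labels says whether the libraries of a stage came from separate cultures. The submitters' processing notes name Bowtie2, bedtools and MACS2, without version, role or settings. The genome build, any shift of reads for the Tn5 insertion site, the treatment of duplicate and multiply mapped reads, and the calling settings are not given in the sources used here.

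The authors deposited 1 list of peaks per stage, which they named as IDR peaks. IDR, the irreproducible discovery rate, ranks the peaks of replicates against each other and keeps those that rank alike. Whether peaks were called on each library or on pooled libraries before that step is not given in the sources used here. The lists have 12 columns without a header, in the order of the output of the IDR tool. In that layout the deposited score is a capped transform of the IDR (at most 1000), and another deposited score column holds −log10 of the global IDR. The deposited enrichment is a fold over background, the deposited significance is −log10 of a p-value, and a further column gives the summit offset. The deposited score followed from the deposited IDR to within 1 unit in all 202721 peaks. The highest IDR in a list was 0.100, so weaker peaks are absent from all lists. The number of peaks in a list can depend on this threshold, on depth and on the agreement between replicates as well as on the chromatin itself. Depth cannot be read from the lists, and no effect of depth was corrected.

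Starts were converted to 1-based positions. Scaffold names carry a length, and 12 scaffolds held peaks beyond it, by up to 40718 bp, so the larger of the named length and the last peak end was used. Overlapping peaks within a list were to be merged for the covered length, but no list held any. Sharing was counted as an overlap of at least 1 bp, with Wilson 95% intervals that cover counting error only, and as the Jaccard index over base pairs. Chance sharing came from 100 random placements within scaffolds. A displacement of 5000 to 10000 bp to either side was added after the data were seen. Consensus regions were the union of the 4 lists, merged where peaks overlapped by at least 1 bp, and a region was present at a stage where a peak of that stage overlapped it. Peaks were ranked by score, with ties at the maximum resolved by −log10 p, then enrichment, then position. This tie rule was chosen after the lists were seen. The words strength, strong and weak below refer to this rank, which rests first on the IDR and not on enrichment. Peaks are not replicates, so no p-value was computed between stages.

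The sites named in the report follow a rule fixed before the data were examined: the 3 peaks of highest score per stage among regions of that stage alone and the 3 among regions of all 4 stages. All 24 sites had the maximum score, so which of the tied peaks were named rests on the later tie rule. Comparisons with gene lists, genomic location and sequence motifs had been planned as well. They were not run in that form and enter no result here, because no build is named for the lists. An exploratory overlay of the lists on RefSeq gene positions, made after the data were seen, is left out for the same reason. The test of neighbouring regions shuffled the stage patterns within scaffolds 100 times, also within 10 classes of strength, and also with regions of all 4 stages held in place.

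The overlap and pattern steps were run on simulated data with 60000 regions on the real scaffolds, and 100% of the patterns were recovered. These regions lay so far apart, with edges moved so little, that this recovery was fixed by the layout. Merging of regions that lie close together was not tested. When 20% of simulated mid gastrula peaks were removed at random, 20.2% was estimated from the gaps, given the share of gaps before removal. In the real lists that earlier share is unknown, and gaps fell mostly on low-ranked regions. The simulation therefore does not say how many real peaks were missed. The test of neighbouring late gastrula regions exceeded all shuffles in 0 of 20 simulations in random order. It did so in 20 of 20 in which 10% of these regions were given a neighbour. Only the plain shuffle within scaffolds and this size of effect were simulated. Shuffles that hold strength or constant regions were not. Alternatives were stricter lists, equal list lengths, strong peaks alone, other overlap rules, fixed windows of 200 bp around summits, and each stage left out for the count of gaps. Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.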

Results

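Chromatin accessibility was profiled by ATAC-seq in whole embryos of the acorn worm Ptychodera flava, a hemichordate and thus an invertebrate deuterostome, through early development. In ATAC-seq the Tn5 transposase inserts sequencing adapters into DNA that is not packed in nucleosomes, so a peak marks an accessible stretch of chromatin. The samples covered 4 stages, the early blastula (a hollow ball of cells before gastrulation) and the early, mid and late gastrula (successive steps of the infolding that forms the gut), with 2 libraries per stage and 8 in all. Each stage was represented by 1 list of peaks, which gives no value per replicate. Differences between stages therefore have no replicate check. The lists give no read counts, so the sequencing depth of the libraries is unknown, and every interval below covers counting error of peaks only. Scores, enrichment values and −log10 p are those the authors deposited for each peak, and they were used here only to describe or rank peaks within a list. Coordinates are 1-based positions on the scaffolds as named in the lists. The genome build is not given in the sources used here, and gene positions enter no result here.

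The late gastrula list held the most peaks and the mid gastrula list the fewest. The early blastula list held 46275 peaks, the early gastrula list 48416, the mid gastrula list 43317 and the late gastrula list 64713. They covered 16.1, 16.3, 14.7 and 20.3 Mb in that order. Peaks were narrowest at late gastrula, with a median width of 273 bp, against 293 bp at early blastula, 290 bp at early gastrula and 299 bp at mid gastrula. Very broad peaks, longer than 1000 bp, were most frequent at early blastula: 393 there (0.849% of its peaks), 198 at early gastrula (0.409%), 118 at mid gastrula (0.272%) and 135 at late gastrula (0.209%). Between 88.1% and 90.9% of these broad peaks, depending on the stage, lay in regions that held a peak at all 4 stages. Of all peaks, 25003, 25482, 25372 and 26033 lay in such regions, from early blastula to late gastrula. A wider peak also meets the overlap rule more easily. The order of the stages by number of peaks was the same among peaks with an irreproducible discovery rate of at most 0.01, which numbered 22783, 25100, 21600 and 33212.

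Peaks were spread unevenly over the scaffolds. Of the 202721 peaks, 98.3% lay on the 27 scaffolds of at least 10 Mb. Scaffold 14 was the most densely occupied of these in every list, from 60.4 peaks per Mb at mid gastrula to 86.4 at late gastrula, with 66.7 at early blastula and 68.3 at early gastrula. Scaffold 26 was the sparsest in every list, with 13.4, 13.7, 12.2 and 19.7 peaks per Mb from early blastula to late gastrula. The ratio of late gastrula to early blastula peaks was above 1 on 27 of the 27 scaffolds and ranged from 1.24 on scaffold 27 to 1.49 on scaffold 11. The ratio of mid to early gastrula peaks was below 1 on all 27 and ranged from 0.828 on scaffold 3 to 0.947 on scaffold 23. The early gastrula list held more peaks than the early blastula list on 25 of the 27 scaffolds, with scaffold 24 lowest at a ratio of 0.908 to early blastula. All scaffolds draw on the same lists, so these ratios carry the difference in list lengths and are not independent of each other.

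**Figure D1:**
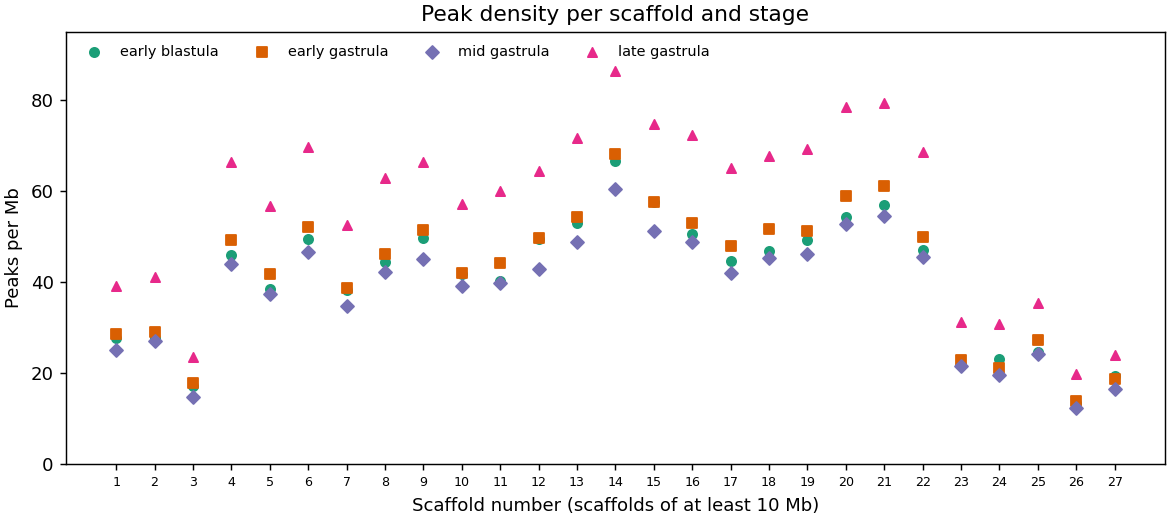
Peaks per Mb (vertical axis) on each of the 27 scaffolds of at least 10 Mb (horizontal axis, scaffold number), with 1 symbol per stage and no error bars, since each stage has 1 list. The late gastrula symbol lies above the early blastula symbol on every scaffold, and scaffold 14 is highest and scaffold 26 lowest at each stage.

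The next comparison asked how much of the accessible landscape each pair of stages shared. Most mid gastrula peaks had a late gastrula counterpart: 90.3% of mid gastrula peaks overlapped a late gastrula peak by at least 1 bp (Wilson 95% interval 90.03 to 90.59). The reverse share was 61.0% (60.6 to 61.4). Of the early blastula peaks, 72.1% (71.7 to 72.5) overlapped an early gastrula peak, and of the early gastrula peaks 68.7% (68.3 to 69.1) overlapped a mid gastrula peak. By base pairs, the Jaccard index was lowest between early blastula and late gastrula, at 0.381, and next lowest between early blastula and mid gastrula, at 0.412. It was 0.506 between early blastula and early gastrula, 0.539 between early and mid gastrula, and 0.555 between mid and late gastrula. Between early and late gastrula it was 0.486. From early blastula to late gastrula 70.1% of peaks were shared (69.7 to 70.5), and in the other direction 51.7% (51.4 to 52.1). Fewer early blastula peaks, 60.1% (59.6 to 60.5), were shared with mid gastrula, the shortest list. Peaks placed at random within their scaffolds were shared in 2.67% to 4.001% on average over 100 placements, depending on the pair. Peaks displaced by 5000 to 10000 bp, which stay in their neighbourhood, were shared in 5.41% to 8.33%. A share depends on the length of the other list. The Jaccard index depends on the covered lengths of both lists, and it was not computed at equal list lengths. With all lists shortened to their 43317 highest-ranked peaks, mid gastrula sharing with late gastrula was 79.1% and early blastula sharing with late gastrula 60.3%. Early blastula sharing with early gastrula was then 71.1%, below early gastrula sharing with mid gastrula at 73.3%, the reverse of their order in the whole lists.

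Merging the lists gave 82811 consensus regions, and these fell mainly into a constant and a stage-restricted class. Regions with a peak at all 4 stages numbered 24094 (29.1%). Regions with a peak at 1 stage numbered 29913 (36.1%), of which 15453 belonged to late gastrula, 8458 to early blastula, 4197 to early gastrula and 1805 to mid gastrula. Another 16104 regions had peaks at 2 stages and 12700 at 3. Among these, 6354 regions were in the early, mid and late gastrula lists alone and 5996 in the mid and late gastrula lists alone. Both patterns outnumbered the regions in the early blastula and early gastrula lists alone (3643). The late gastrula list is the longest; at equal list lengths these patterns had 5277, 5033 and 4210 regions. The lead of late gastrula over early blastula among stage-restricted regions turned round at equal list lengths, where 5013 belonged to late gastrula and 9261 to early blastula. That shortening took away 70.2% of the peaks of late gastrula alone and 16.7% of those of early blastula alone.

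**Figure D2:**
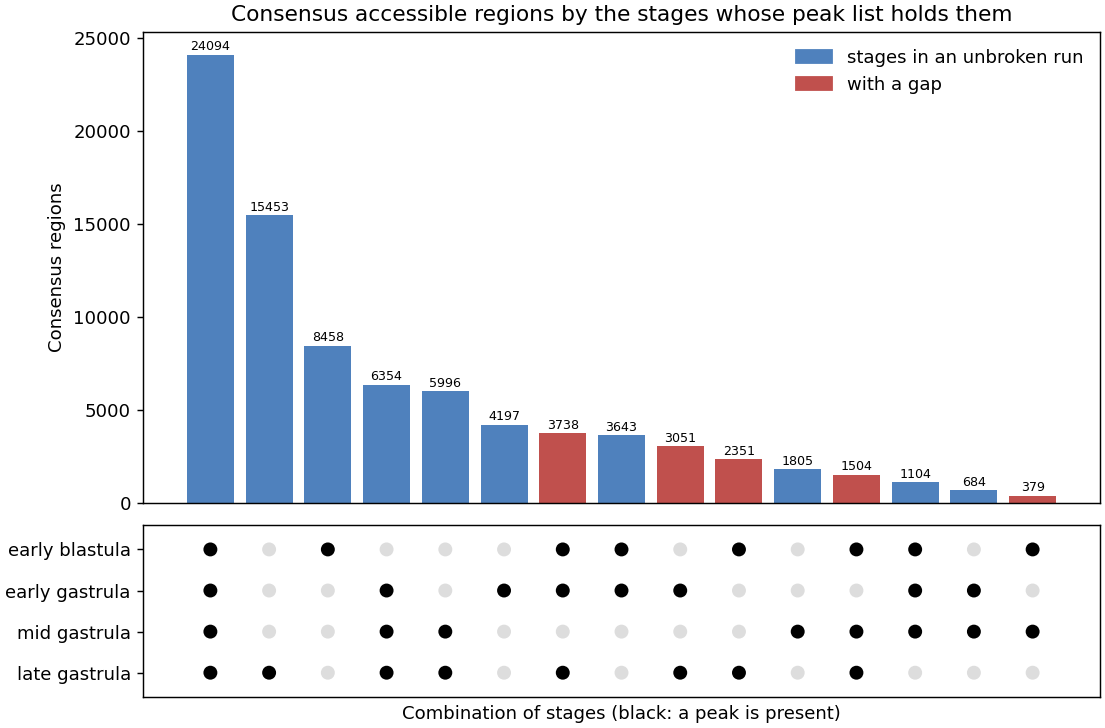
Number of consensus regions (vertical axis) for each of the 15 combinations of stages, with black dots below each bar marking the stages whose list held a peak. Blue bars are unbroken runs of stages and red bars the 5 combinations with a gap; the regions of all 4 stages (24094) and of late gastrula alone (15453) form the tallest bars.

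Patterns with a gap, in which a region was absent between stages that held it, comprised 11023 regions (13.3%). At equal list lengths they numbered 5970. With 1 stage left out, which allows fewer such patterns, they numbered 6936 without early blastula, 6111 without early gastrula, 3885 without mid gastrula and 1894 without late gastrula. Of the 37237 regions with a peak at both early and late gastrula, 6789 had none at mid gastrula (18.2%, 17.8 to 18.6). The missing share was 49.5% among the weakest of 5 equal classes of these regions, by rank in the early and late gastrula lists, and 0.269% among the strongest. Of the 27081 regions with a peak at both early blastula and mid gastrula, 1883 had none at early gastrula (6.95%, 6.66 to 7.26).

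At each developmental step some regions were gained and others lost between the lists, and the balance of a step followed the lengths of its lists. From early blastula to early gastrula 14286 consensus regions were gained and 12692 lost. From early to mid gastrula losses exceeded gains, with 9684 gained and 14629 lost. From mid to late gastrula 24593 were gained and 3972 lost, so that 90.5% of the mid gastrula regions were kept. Between the end points, early blastula and late gastrula, 30854 regions were gained and 13584 lost. Gained and lost here mean that a region had a peak in the later or the earlier list alone. A region without a peak in a list may be accessible but below its threshold. Consecutive steps share a list, so a region of early gastrula alone counts as gained in one step and lost in the next. Equal list lengths make gains and losses nearly equal by construction. Gained and lost regions were then 11891 and 12328 from early blastula to early gastrula, 11123 and 11151 from early to mid gastrula, 8766 and 8695 from mid to late gastrula, and 16506 and 16900 from early blastula to late gastrula. The ratio of gained to lost was 0.965 in place of 1.13, 0.997 in place of 0.662, 1.01 in place of 6.19 and 0.977 in place of 2.27 for these pairs. Strong peaks, the upper 50% of each of these equal lists, were compared with the whole of the other equal list, a comparison added after the data were seen. Those without a counterpart numbered 2412 gained and 1835 lost from early blastula to early gastrula (ratio 1.31), and 1673 and 1688 from early to mid gastrula (0.991). They numbered 1040 and 674 from mid to late gastrula (1.54), and 5159 and 4568 from early blastula to late gastrula (1.13).

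**Figure D3:**
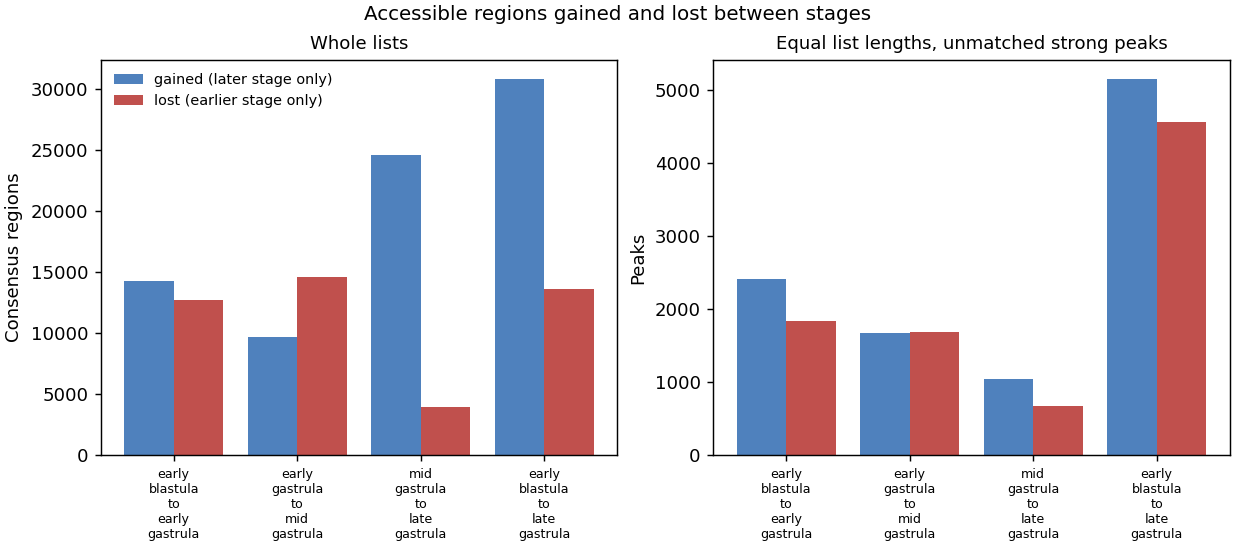
Regions gained (blue) and lost (red) for each pair of stages, as consensus regions from the whole lists (left) and, with all lists at equal length, as strong peaks, the upper 50% of a list, with no peak in the other list (right). The balance on the left, such as 24593 gained and 3972 lost from mid to late gastrula, carries the difference in list lengths; on the right the same pair has 1040 and 674.

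Of the 14286 regions gained at early gastrula, 44.5% had a peak at both mid and late gastrula and 29.4% at no later stage. In all 65.8% had one at late gastrula, the longest list, including 3051 regions without a peak at mid gastrula. Of the 12692 regions lost at early gastrula, 66.6% had no peak at mid or late gastrula. Of the 9684 regions gained at mid gastrula, 77.4% were kept at late gastrula. Of the 14629 lost at mid gastrula, 46.4% had a peak again at late gastrula. Of the 24593 gained at late gastrula, 9140 (37.2%) had already had a peak at early blastula or early gastrula.

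Stage-restricted peaks ranked lower in their own list than peaks in regions of all 4 stages. Membership of these classes depends on passing the IDR threshold of each list. A peak ranked near that threshold can thus be missed in the other lists without any change between stages, and a top-ranked peak is likely to recur. The rank gap therefore describes the classes and cannot tell missed weak peaks from a change in accessibility. Peaks of early blastula alone had a median percentile of 21.7 by rank within their list, against 68.1 for early blastula peaks in regions of all 4 stages. The corresponding medians were 16.4 and 69.9 at early gastrula, 11.7 and 65.8 at mid gastrula, and 21.3 and 74.5 at late gastrula. Stage-restricted peaks were also narrower, with a median width of 249 bp against 332 bp at early blastula and 235 bp against 306 bp at late gastrula. Their median enrichment was lower at each stage. It was 6.16 against 7.56 at early blastula and 6.96 against 9.14 at early gastrula. At mid gastrula it was 7.21 against 9.33, and at late gastrula 6.49 against 9.19. The maximum score was shared by 37.4%, 39.7%, 38.2% and 39.5% of the peaks from early blastula to late gastrula, so percentiles above about 60 rest on −log10 p, a tie rule chosen after the lists were seen. By score alone, 5.97% of peaks of early blastula alone had the maximum, against 57.4% of early blastula peaks in 4-stage regions. These shares were 2.93% and 63.6% at early gastrula, 1.77% and 55.1% at mid gastrula, and 4.50% and 70.4% at late gastrula.

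**Figure D4:**
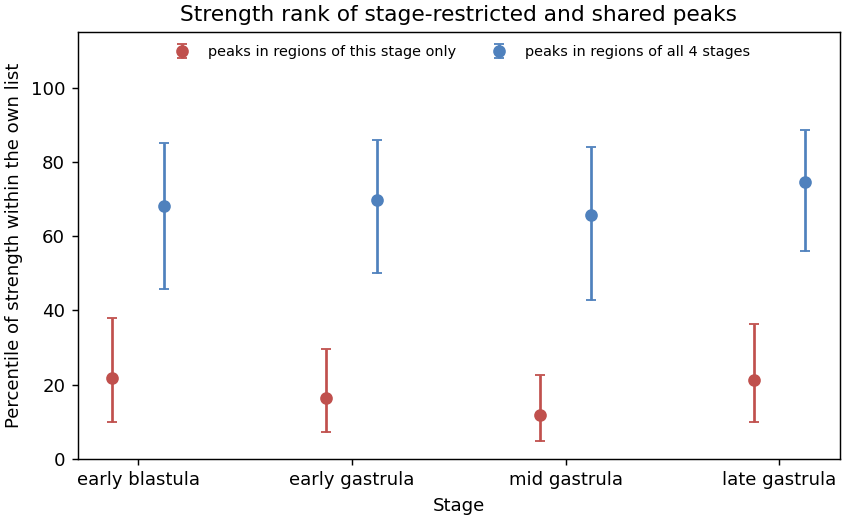
Percentile of strength within the own list (vertical axis, 100 is strongest) for peaks in regions of that stage alone (red) and in regions of all 4 stages (blue), for each stage. Strength here is the rank by the IDR-based score, with ties resolved by −log10 p, and not enrichment. Points are medians and bars span the quartiles of peaks, not an error between replicates; medians of stage-restricted peaks lie between 11.7 and 21.7 and those of shared peaks between 65.8 and 74.5.

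A site on scaffold 5 was among the 3 leading constant sites of each list. The order of the sites named here rests on −log10 p, since all of them had the maximum score of 1000. The peak at 37786517 to 37786923 ranked highest among the 4-stage peaks at late gastrula, with a −log10 p of 153 and an enrichment of 25.6. The corresponding peak ranked highest at mid gastrula (37786515 to 37786879, −log10 p 160, enrichment 29.6) and took rank 3 at early gastrula (37786517 to 37786890, −log10 p 136, enrichment 27.8) and at early blastula (37786519 to 37786928, −log10 p 127, enrichment 25.9). It stood in a sparse neighbourhood, with 2 peaks, itself included, within 50 kb on each side in every list. Ahead of it at early blastula were scaffold 7, 47266591 to 47267024 (−log10 p 130, enrichment 15.9), and scaffold 2, 2129350 to 2129782 (−log10 p 128, enrichment 25.5). Ahead of it at early gastrula were scaffold 4, 44162996 to 44163368 (−log10 p 142, enrichment 27.9), and scaffold 71, 48346 to 48701 (−log10 p 137, enrichment 27.0). The scaffold 71 site was also second at mid gastrula, at 48346 to 48702 with a −log10 p of 144 and an enrichment of 28.2. Rank 3 at mid gastrula was on scaffold 17 at 38423411 to 38423831 (−log10 p 142, enrichment 22.2). At late gastrula the next ranks went to scaffold 11, 42911431 to 42912144 (−log10 p 148, enrichment 25.2), and scaffold 17, 17305146 to 17305507 (−log10 p 147, enrichment 28.6).

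The leading site of early blastula alone was on scaffold 3 at 33348199 to 33348551, with a −log10 p of 93.7 and an enrichment of 20.5, and the nearest peak of another stage was 25759 bp away. Next came scaffold 9, 7767488 to 7767844 (−log10 p 73.9, enrichment 19.9), and scaffold 4, 10838802 to 10839107 (−log10 p 69.9, enrichment 18.0). The scaffold 4 site was isolated, with no other peak in any list within 50 kb and the nearest peak of another stage 206730 bp away.

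The leading sites of late gastrula alone were on scaffold 1 at 15015043 to 15015691 (−log10 p 82.6, enrichment 16.8), scaffold 5 at 11971497 to 11971803 (−log10 p 74.3, enrichment 13.1) and scaffold 13 at 36938759 to 36939203 (−log10 p 73.8, enrichment 13.2). The nearest peaks of other stages were 45842, 1072 and 9860 bp away. The scaffold 5 site stood in a densely occupied neighbourhood, with 17 late gastrula peaks, itself included, and 17 early blastula peaks within 50 kb on each side.

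The leading sites of early gastrula alone were on scaffold 21 at 17818643 to 17819184 (−log10 p 74.6, enrichment 13.8), scaffold 34 at 2288255 to 2288668 (−log10 p 56.7, enrichment 15.6) and scaffold 6 at 42747357 to 42748210 (−log10 p 53.5, enrichment 14.5). The scaffold 34 site lay only 60 bp from a peak of another stage. Those of mid gastrula alone were on scaffold 17 at 36508332 to 36508713 (−log10 p 53.3, enrichment 18.3), scaffold 20 at 32213994 to 32214430 (−log10 p 40.2, enrichment 14.1) and scaffold 7 at 14046464 to 14046709 (−log10 p 32.8, enrichment 9.40). The scaffold 7 site lay 242 bp from a peak of another stage. These mid gastrula sites ranked at the 84.6, 71.8 and 64.1 percentiles of their list.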

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

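The alternatives for the named sites, for strong peaks at equal list lengths, for averaged score ties, for scaffolds of at least 10 Mb and for a peak covering at least 50% of its consensus region were chosen after the data were seen; the others were fixed before. The last replaced the planned 50% of the shorter interval, which changes nothing because every peak lies inside its region. No paired analysis was possible because each stage has 1 list and the lists carry no values per replicate; for the same reason no replicate was left out. Alternatives that had been planned for genomic location, gene lists and motifs were not run in that form, and those tried with the exploratory overlay on gene positions are left out with it. Of 171 values under alternatives, 3 changed direction, all of them ratios at equal list lengths. Only ratios and rank gaps could change direction. Counts, shares and the checks of named sites could not, so the 171 values are no measure of how stable the directions were. At equal list lengths the ratio of regions of late gastrula alone to those of early blastula alone was 0.541 instead of 1.83. The ratio of gained to lost regions was there 0.965 instead of 1.13 from early blastula to early gastrula, and 0.977 instead of 2.27 from early blastula to late gastrula. Equal lengths force the ratio of gained to lost near 1 by construction. Depth, which is unknown, limits every count. The 36 checks of named stage-restricted sites used shorter lists or windows, which leave little room for change, and say nothing about stability. Merging overlapping peaks could change no count, because no peaks within a list overlapped. The rank gap between 4-stage and stage-restricted peaks stayed within 1.5 times its value among wider peaks and with score ties averaged.

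Values that moved beyond 1.5 times, or for shares beyond their counting interval, follow in stage order. With an IDR of at most 0.01 the lists held 22783, 25100, 21600 and 33212 peaks, fewer by construction. Shares are given for early blastula in early gastrula, early in mid gastrula, mid in late gastrula and early blastula in late gastrula. With reciprocal overlap of 50% they were 67.0%, 65.1%, 86.4% and 62.8%. With 200 bp around the summit they were 69.7%, 66.7%, 88.4% and 67.1%. At equal list lengths they were 71.1%, 73.3%, 79.1% and 60.3%.

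At equal list lengths 3873 regions belonged to mid gastrula alone, 5013 to late gastrula alone and 5970 had a gap. From mid to late gastrula 8766 were then gained and 8695 lost (ratio 1.01 instead of 6.19), and from early blastula to late gastrula 16506 were gained. From early to mid gastrula 11123 gained and 11151 lost gave 0.997 instead of 0.662. With the upper 50% of each list, 12883 regions had all 4 stages and 14026 had 1 stage, of which 4061, 1647, 495 and 7823 belonged to the stages in order, and 4589 had a gap. Gained and lost regions there were 6670 and 5774 from early blastula to early gastrula, 4035 and 6540 from early to mid gastrula, 11726 and 1334 from mid to late gastrula, and 15424 and 6641 from early blastula to late gastrula. These lists are shorter by construction. Counted as strong peaks with no peak in the other whole list, gains and losses were 2914 and 1817, 1417 and 2321, 3644 and 319, and 9596 and 3452 for the same pairs, with a ratio of 11.4 from mid to late gastrula; this keeps the unequal list lengths. At equal lengths they were 2412 and 1835, 1673 and 1688, 1040 and 674 (ratio 1.54), and 5159 and 4568 (ratio 1.13). Regions with a gap numbered 6936, 6111, 3885 and 1894 with early blastula, early, mid or late gastrula left out, since 3 stages allow fewer such patterns.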

Other observations

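The tests of list length and of neighbouring late gastrula pairs were chosen after the result was seen; the other tests were chosen after the patterns were noticed, with the deciding values set before each test was run. No biological explanation can be separated from the stage lists by replicates, and each statement below is a hypothesis about these 4 lists.

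Windows dense in regions of 1 stage alone held no more such regions than the densest windows of shuffled patterns. The 100 kb window with most regions of late gastrula alone was on scaffold 6 from 25100001 to 25200000, with 14 such regions among 28. It held 25 late gastrula peaks against 11 at early blastula, a difference that follows from how the window was picked. A window on scaffold 13 from 33700001 to 33800000 also held 14, among 31. For early blastula alone the leading window was on scaffold 85 from 200001 to 300000, with 9 of 25 regions. Shuffled patterns gave up to 15 late gastrula and up to 14 early blastula regions in a window.

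Regions of the same pattern lay next to each other more often than in shuffled patterns, with 3405 neighbouring pairs of late gastrula regions against at most 2992 in 100 shuffles within scaffolds, 1171 of early blastula regions against at most 940, and 8007 of regions of all 4 stages against at most 7168. Splitting of 1 accessible stretch into adjacent peaks is argued against for late gastrula by 2276 pairs at least 2 kb apart, above the shuffled maximum of 1980. At mid gastrula 37 such pairs against at most 39 do not decide it. These were few, at 1.43 times the shuffled mean, against 1.21 times at late gastrula. As whole causes for late gastrula, weak regions lying side by side (at most 3053 pairs in shuffles within classes of strength) and constant regions lying side by side (at most 3088 with these also held in place) are argued against too. With distance, strength and constant regions all held, 2276 late gastrula pairs stood against at most 2226. Early blastula had 790 against 685, early gastrula 201 against 193, and mid gastrula 37 against 42. The ratios to the shuffled mean were 1.07 at late gastrula, 1.23 at early blastula, 1.24 at early gastrula and 1.28 at mid gastrula. Only the mid gastrula count did not exceed all shuffles. Neighbouring regions may thus share a stage pattern to a small degree, least at late gastrula by this ratio. Regional effects of mapping or copy number were not tested.

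Regions absent at mid gastrula between early and late gastrula lists that held them were mostly weak. In the weakest of 5 equal classes of the 37237 regions, ranked by the lower of their early and late gastrula percentiles, 49.5% were missing at mid gastrula; in the strongest class it was 0.269% (20 of 7448). This argues against a closing at mid gastrula of regions of every strength and is consistent with weak regions falling below the threshold of the shortest list. A closing confined to weak regions stays open, as does a lower depth of the mid gastrula libraries, which is unknown.

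More regions belonged to late gastrula alone than to early blastula alone, by 1.83 times. At an equal length of 43317 peaks the ratio was 0.541, but this does not decide whether list length accounts for the excess, because the shortening itself removed 70.2% of the peaks of late gastrula alone. Why that list is longer, through depth, replicate agreement or more accessible sites, stays open. Strong peaks with no peak in any other whole list numbered 51.1 per 1000 at late gastrula and 49.1 per 1000 at early blastula. Early and mid gastrula had 11.3 and 3.51 per 1000, and as the inner stages of the series they have a neighbour on both sides. The lists were of unequal length. Late gastrula peaks were sought only in shorter lists and early blastula peaks also in the longest, which favours late gastrula. The ratio of late gastrula to early blastula, 1.04, lies between the values set for and against strong regions opening at late gastrula. It does not decide whether such regions opened. In counts these strong peaks were 1654 and 1136, beside 15453 and 8458 regions of the same stages alone. Most of the excess thus lay outside strong peaks, which argues against strong regions as its main source.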
